A study of Mus musculus with 8 samples.

How the data were processed

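Total RNA was extracted with a miRNeasy kit, mRNA was reverse-transcribed and amplified by the Geo-seq method, and libraries were made with a transposase kit (TruePrep), per the labels' protocols. No molecular identifiers are described, so PCR copies count as separate reads. The authors deposited 1 table of raw read counts per gene symbol for 8 libraries. The submitters' processing notes name Bowtie 0.12.9, HTSeq 0.13.5, DESeq2 and the mouse build mm10, without role or order, while the sheet name of the deposited counts names featureCounts; which tool counted the reads is therefore unresolved. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Unstranded counting would merge genes that overlap on opposite strands, and reads shared by near-identical copies may have been dropped or assigned to either copy.

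The table held 55291 genes, and every entry named a gene. Its columns are named knockout 1 to 4 and wild type 1 to 4, whereas the labels name the control group FL; the wild type columns were taken as FL because it is the only group without the knockout, with the same numbers. Gene positions, types, exonic lengths and GC content came from GENCODE M21 on the same build, matched by symbol for 53292 genes (96.4%), of which 106 symbols were ambiguous. Totals were 33941940 to 58660705 counts per library. Because PCR copies count as reads, these totals do not bound the error from sampling molecules. The tests take their precision from the spread between libraries.

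KO was compared with FL, 4 libraries each, with edgeR 4.0.16 in R 4.3.3: TMM factors, genes kept by filterByExpr, a quasi-likelihood F test with no covariate, and Benjamini-Hochberg adjustment over the kept genes at a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values of single genes are scaled by TMM factors, which were 0.68 to 0.91 in FL and 1.20 to 1.26 in KO. Summed CPM of receptor genes and of sense intronic transcripts are per total counts, without TMM factors. No library was a copy of another: the lowest chi-square per degree of freedom of a pair within a group was 21.2, over genes with 20 or more counts. Pearson correlations of log2 CPM were 0.975 to 0.988 within FL, 0.977 to 0.991 within KO and 0.938 to 0.961 between groups, and the first principal component of the 500 most variable genes held 79.3% of the variance.

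Before the data were examined, 35 gene lists were fixed, covering the MLL-AF9 program, stem cell genes, sort markers, blood lineages, cell cycle, metabolism, translation, interferon, stress, DNA repair and chromatin. The 34 lists with 3 or more kept members were tested with limma 3.58.1's camera at an inter-gene correlation of 0.01. With a correlation estimated from the data, 0 lists passed (1 at an unadjusted p under 0.05), against 10 with the preset correlation. The fry test, which asks whether a list's genes move one way on balance, passed 13 lists (4 up, 9 down).

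The genes named were taken from Dek and Pbx3; the 12 largest rises and 12 largest falls among called genes with no overlap between groups, a mean of 5 CPM or more and a symbol that is not a predicted or clone name (768 and 1557 genes met these conditions); Hoxa9, Hoxa10, Meis1, Cdk6, Myb and Mef2c; up to 4 members of each list by smallest p; and the most abundant gene. Rps4l and Vegfa, which moved against their lists, were named after their values were seen.

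Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile factors, no count filter, a stricter filter of 5 CPM in 4 libraries, the replicate number as a block, the number of genes detected as a covariate, a fold change limit, and each library left out in turn. Total-count scaling, leaving out KO replicates 2 and 3 together, and a test against a log2 fold change of 1 were added after the data were seen. The edgeR, DESeq2, voom and camera steps were tested on simulated data for this comparison, 17420 genes with 200 changed: edgeR recovered 54% of genes changed 2-fold and 84% of those changed 4-fold with 6.58% false calls, DESeq2 72% and 91%, and voom 51% and 82%. The edgeR figures count only calls in the right direction, and those of DESeq2 and voom count calls in either direction. False calls were counted for edgeR alone, so these figures do not rank the tools. The seeded list was found and 0 of 20 random lists were called. The simulated genes were drawn independently of each other, and far fewer were changed than the 4853 called in the data. Estimated correlations within lists were 0.73 for ribosomal protein genes and 0.10 for glycolysis genes. The simulation therefore does not bound false calls of correlated lists.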

Results

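RNA sequencing was performed on leukaemic granulocyte-macrophage progenitors (L-GMP) of mice with acute myeloid leukaemia driven by MLL-AF9, a fusion oncogene that keeps HOXA and MEIS1 target genes active. The cells came from bone marrow and had been sorted as negative for lineage markers and Sca-1 and positive for c-Kit, CD16/32 and CD34; the labels call them leukaemia stem cells. The 8 libraries fell into 2 groups of 4. FL libraries came from mice with floxed Dek alleles alone, and KO libraries from mice that also carried Mx1-Cre, a transgene used to delete floxed alleles in blood cells. DEK is a chromatin-bound protein and histone chaperone. The series title links DEK, its phosphorylation by the kinase CK2 and overexpression of PBX3. The comparison of KO with FL therefore bears on what loss of Dek does to the L-GMP transcriptome and to Pbx3. Only KO mice carried Mx1-Cre, so an effect of that transgene cannot be told apart from Dek loss. Library totals were 44086524 to 58660705 counts in FL and 33941940 to 49736592 in KO. The labels do not say whether the 4 libraries of a group came from separate mice or leukaemias, so p-values measure the spread between these libraries, which may be technical. The most abundant gene was CT010467.1, an rRNA-type transcript, in both groups, at 61775 CPM (counts per 1e6, scaled by TMM) in FL and 25983 CPM in KO.

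Dek transcripts fell in KO L-GMP, and Pbx3, which encodes a homeodomain cofactor of HOX proteins, fell further, to a mean of 0.749 CPM. The eosinophil granule genes Epx and Prg2 and 16 of the 29 measured type I interferon genes rose. Epx and Prg2 were highest in KO replicates 2 and 3. With the number of genes detected as a covariate they had log2 fold changes of 0.90 and 0.013 and did not pass. Genes for ribosomal proteins, oxidative phosphorylation, glycolysis, DNA replication and cholesterol synthesis were lower as lists under TMM scaling. With an estimated correlation none of these lists passed (adjusted p = 0.589 for each). Under total-count scaling the oxidative phosphorylation and replication medians turned to 0.03 and 0.09. Those of ribosomal proteins, glycolysis and cholesterol synthesis were -0.60, -0.16 and -0.03 in place of -1.23, -0.74 and -0.61. The core MLL-AF9 genes Hoxa9 and Hoxa10 differed by less than the test could call. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4853 of 17418 genes passed an adjusted p of 0.05, 2256 higher and 2597 lower in KO. With the number of genes detected as a covariate 205 passed. That number was 24125 to 26053 in FL and 30606 to 37801 in KO, so the covariate follows the groups closely. A call lost with it, here and below, cannot tell an effect of library breadth from a difference between the groups.

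Dek lies on chromosome 13 from 47084775 to 47106201 (mm10, protein coding). Its level was 129, 137, 163 and 178 CPM in the FL libraries and 21.2, 21.4, 31.0 and 16.7 CPM in the KO libraries, a mean of 151.7 ± 22.7 against 22.5 ± 6.03 CPM (SD, n = 4 each). The log2 fold change was -2.75 (SE 0.19, adjusted p = 1.7e-05), or 6.73-fold lower, and every KO library lay below every FL library, in the direction of the labels. Dek passed under all 18 alternatives, with log2 fold changes of -3.48 to -2.15 (adjusted p 1.3e-60 to 0.0045). The labels do not name the deleted exons, so the gene-level count can include reads from the rest of the transcript. Pbx3, on chromosome 2 from 34171457 to 34373142, averaged 32.4 ± 3.14 CPM in FL and 0.749 ± 0.386 CPM in KO (SD, n = 4 each). Its log2 fold change was -5.44 (SE 0.37, adjusted p = 1.5e-05), or 43.4-fold lower, and it passed under the same 18 alternatives (adjusted p 2.6e-113 to 0.014). Dek and Pbx3 overlap Kdm1b and C79798 on the opposite strand, whose log2 fold changes were 0.09 and -5.48, and reads of overlapping genes could not be told apart because the strand setting of the counting was not given.

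**Figure D1:**
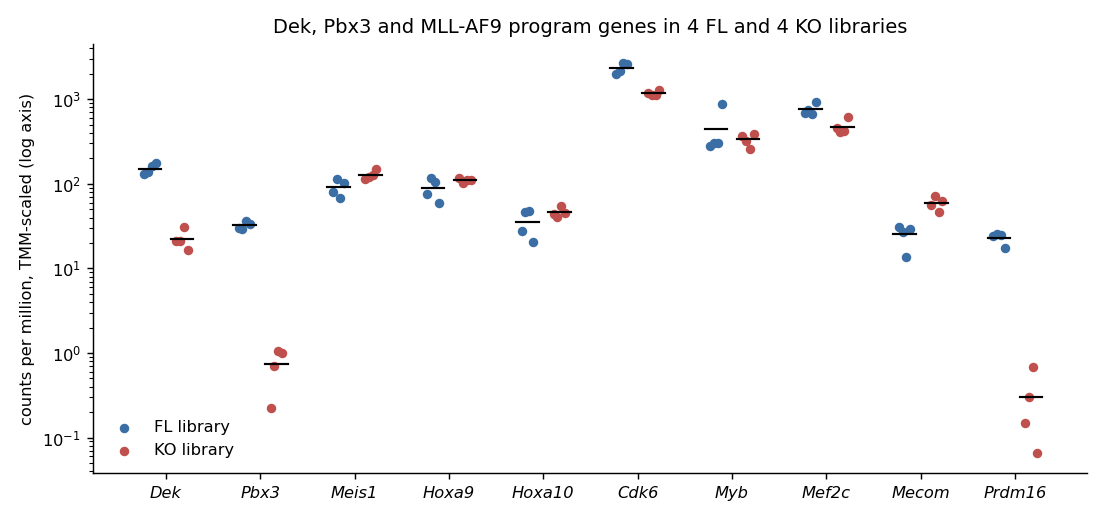
Levels of Dek, Pbx3 and 8 further MLL-AF9 or stem cell genes in TMM-scaled CPM on a log axis, with 1 point per library (4 FL in blue, 4 KO in red) and a bar at each group mean. Dek and Pbx3 are lower in all 4 KO libraries, Hoxa9 and Hoxa10 overlap between groups, and 1 FL library stands far above the others for Myb, whose mean is lower in KO here and higher in KO under total-count scaling.

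Of the 18 measured genes of the MLL-AF9 program, 5 rose and 4 fell (6 and 4 adjusted over the list alone; 11 and 3 under total-count scaling, where the median was 0.65), and the list as a whole did not pass camera (adjusted p = 0.937, median log2 fold change 0.08, mean -0.10). Mecom, a zinc finger factor of stem cells, rose from 25.3 CPM in FL to 59.1 CPM in KO (log2 fold change 1.23, SE 0.23, adjusted p = 0.0032). Cdk6, which drives entry into the cell cycle, fell by 0.99 on the log2 scale (SE 0.13, adjusted p = 4.4e-04). Mef2c fell by 0.67 (SE 0.16, adjusted p = 0.0098), a call lost under total-count scaling and without KO replicates 2 and 3. Meis1 rose by 0.50 (SE 0.17, adjusted p = 0.044), but the call was lost when FL replicate 1 or 3 or any 1 KO library was left out (adjusted p 0.055 to 0.118; 5.8e-04 to 0.54 over all alternatives). Hoxa9 and Hoxa10 had log2 fold changes of 0.31 (SE 0.19, adjusted p = 0.25) and 0.38 (SE 0.24, adjusted p = 0.27), and both passed as higher under total-count scaling. Myb had -0.40 (SE 0.34, adjusted p = 0.41) with FL replicate 4 at 881 CPM and the other FL libraries between 281 and 304 CPM. Without FL replicate 4 it was 0.16, and under total-count scaling 0.27. Without a count filter edgeR called Myb lower (-0.44, adjusted p = 0.032). Mecom (1.33), Cdk6 (-0.79), Mef2c (-0.16) and Meis1 (0.53) lost their calls with genes detected as a covariate.

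Among the 6 measured PBX, MEIS and PREP cofactors, Pbx3 fell, 3 rose (4 and 1 adjusted over the list alone; 5 and 1 under total-count scaling; 0 rose in edgeR without KO replicates 2 and 3, where 4 members had an unadjusted p under 0.05), and Pknox1 rose by 0.46 on the log2 scale (SE 0.12, adjusted p = 0.014), a call lost without KO replicates 2 and 3. Another member that rose, Pbx2 (0.67, SE 0.19, adjusted p = 0.025), lost its call without FL replicate 1 or 3 or KO replicate 2 or 4 (adjusted p 0.055 to 0.067; 7.5e-04 to 0.44 over all alternatives) and with the replicate block. Of 16 measured stem cell genes, 5 rose and 4 fell (7 and 4 adjusted over the list alone; 9 and 2 under total-count scaling, and 2 and 4 of 9 under the stricter filter). Prdm16, a regulator of stem cell maintenance, fell from 23.1 ± 3.81 to 0.30 ± 0.27 CPM (log2 fold change -6.34, SE 0.50, adjusted p = 3.5e-05). Angpt1 fell by 1.40 (SE 0.24, adjusted p = 0.0016), and Mllt3 rose by 1.83 (SE 0.26, adjusted p = 5.6e-04) to 2.43 ± 0.302 CPM. Transcripts of the 5 sort markers moved apart, 2 up and 2 down by either adjustment and 3 up and 0 down under total-count scaling: Kit rose by 0.75 (SE 0.16, adjusted p = 0.0061) and Ly6a, which encodes Sca-1, by 2.26 (SE 0.54, adjusted p = 0.010) to 1.64 ± 0.871 CPM. Ly6a was at 2.85 without FL replicate 4. Cd34 fell by 0.62 (SE 0.13, adjusted p = 0.0056) and Fcgr3, which encodes CD16, by 0.83 (SE 0.21, adjusted p = 0.012), both calls lost under total-count scaling and without KO replicates 2 and 3. Pbx3 and Prdm16 kept their calls with genes detected as a covariate. Pknox1 (0.48), Pbx2 (0.77), Angpt1 (-1.29), Mllt3 (1.53), Kit (1.22), Ly6a (2.51), Cd34 (-0.24) and Fcgr3 (-0.47) lost theirs, at these log2 fold changes.

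The largest rises that met the naming rule reached a log2 fold change of 10.06. Gdf3, a ligand of the TGF-beta family, went from 0.260 ± 0.205 to 173 ± 30.5 CPM (log2 fold change 9.39, SE 0.39, adjusted p = 4.5e-07). Psma8, a testis proteasome subunit, reached 35.2 ± 4.13 CPM in KO (10.06, SE 0.42, adjusted p = 4.5e-07), and Lipo3, a lipase-like gene, 11.8 ± 3.76 CPM (8.77, SE 0.63, adjusted p = 1.9e-05). Both values rest on few FL reads, a mean of 1.25 per library for Psma8 and 1 for Lipo3, whose FL reads were all in replicate 3. The zinc finger gene Zfp182, the pseudogene Zfp783, the lymphoid factor Bcl11a and the testis gene Nutm1 rose by 7.19, 6.13, 5.78 and 5.10. Without FL replicate 2 the values of Zfp182, Bcl11a and Nutm1 were 9.10, 6.41 and 7.54, and Gdf3 was at 10.04 without FL replicate 4. Psma8 without FL replicate 2 and Lipo3 without FL replicate 3 kept too few FL reads for a fold. Nutm1 was at 3.70 and did not pass with genes detected as a covariate. Ldhb, a lactate dehydrogenase subunit, rose from 5.51 ± 5.51 to 113 ± 32.2 CPM (4.36, SE 0.61, adjusted p = 5.8e-04), with 5.31 without FL replicate 2. With the covariate Ldhb was at 4.43 and its call was lost. The eosinophil genes Epx, Ear6 and Ear2 rose by 4.50, 4.68 and 4.33. Ear genes are near-identical copies that can share reads, and the Ear calls were lost without KO replicates 2 and 3. Without FL replicate 4 the values for Ear6, Ear2 and Epx were 8.48, 6.70 and 5.58, and with genes detected as a covariate they were 0.94, 0.81 and 0.90 and did not pass.

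The 12 largest falls lay between -3.44 and -6.42. Atp9a, a phospholipid-transporting ATPase relative, fell from 50.9 ± 3.13 to 0.593 ± 0.220 CPM (log2 fold change -6.42, SE 0.23, adjusted p = 2.1e-07), 85.8-fold lower. Aspa, which encodes aspartoacylase, and Gal3st1, a sulfatide synthesis enzyme, fell by 5.09 (SE 0.53, adjusted p = 1.2e-04) and 4.88 (SE 0.33, adjusted p = 1.6e-05). Cpa3, a mast cell and basophil protease, fell from 132 ± 69.8 to 5.03 ± 2.88 CPM (-4.71, SE 0.56, adjusted p = 2.3e-04). Lpl (lipoprotein lipase), Jph3 (junctophilin), Fn1 (fibronectin), Tlr13 (an endosomal RNA receptor), Dpysl2 (a microtubule regulator) and Oaf (a secreted protein) had log2 fold changes of -4.05, -4.05, -3.93, -3.61, -3.51 and -3.44. Lpl was at -3.21 without FL replicate 2 and -5.02 without KO replicate 4, and Tlr13 at -4.90 without KO replicate 4. Without KO replicate 3 Prdm16 and Aspa were at -7.11 and -5.74. With genes detected as a covariate the calls of Cpa3, Lpl, Fn1 and Tlr13 were lost, at log2 fold changes of -5.83, -3.62, -5.35 and -1.62. Prdm16 and Pbx3 complete these 12.

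**Figure D2:**
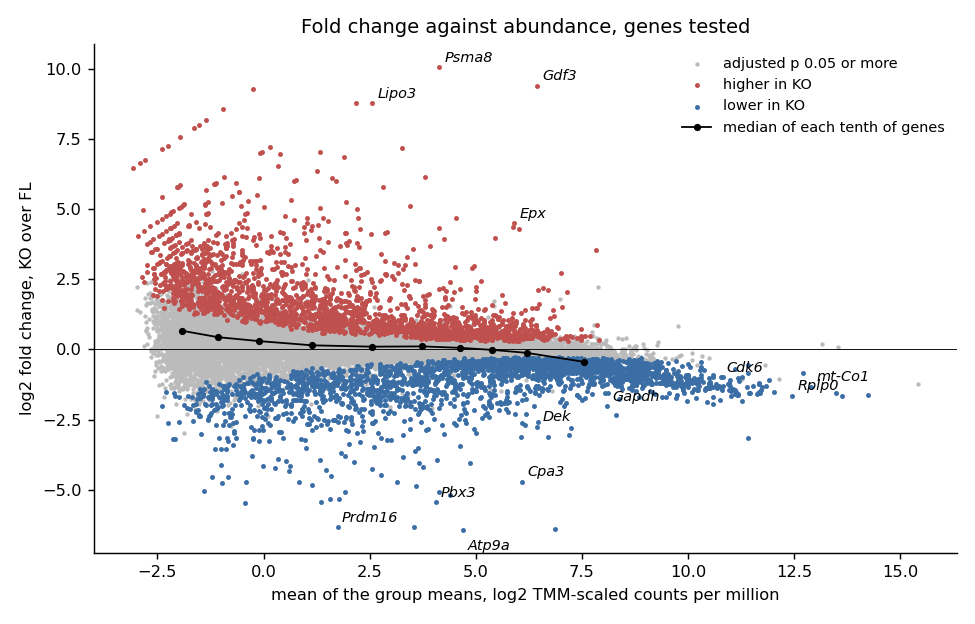
Log2 fold change of KO over FL for each tested gene (vertical axis) against the mean of the group means in log2 TMM-scaled CPM (horizontal axis), with genes past adjusted p 0.05 in red (higher in KO) or blue (lower) and the median of each of 10 abundance bins in black. The median runs from 0.67 in the lowest bin to -0.44 in the highest, where the shift of 0.59 under total-count scaling makes it positive.

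Ribosomal protein genes fell together, 79 of 85 measured, with 1 that rose (80 and 1 adjusted over the list alone; 71 and 2 under total-count scaling). Their median log2 fold change was -1.23, and -0.60 under total-count scaling (camera adjusted p = 1.5e-28, and adjusted p = 0.589 with an estimated correlation). Rplp0 went from 8462 ± 1598 to 2702 ± 232 CPM (-1.65, SE 0.16, adjusted p = 9.1e-05), and Rps2 and Rpl4 had -1.65 and -1.53. The member that rose was Rps4l, annotated as a transcribed processed pseudogene, which reached 0.424 ± 0.176 CPM in KO (3.45, SE 0.68, adjusted p = 0.0039). Of 75 oxidative phosphorylation genes, 62 fell and 0 rose (66 and 0 adjusted over the list alone; 11 and 5 under total-count scaling), with a median of -0.55 that became 0.03 under total-count scaling (camera adjusted p = 1.0e-18, and adjusted p = 0.589 with an estimated correlation). The ATP synthase genes Atp5b, Atp5a1 and Atp5c1 fell by 1.57, 1.37 and 1.17 on the log2 scale. Of 13 mitochondrially encoded mRNAs, 12 fell and 0 rose by either adjustment, and 9 fell and 1 rose under total-count scaling (median -1.25, and -0.64 under total-count scaling; camera adjusted p = 8.9e-08, and adjusted p = 0.589 with an estimated correlation), among them mt-Co1, a cytochrome oxidase subunit, by 1.33 (SE 0.15, adjusted p = 1.8e-04) and mt-Cytb by 1.31. Rplp0, Rps2, Rpl4, Atp5b, Atp5a1, Atp5c1, mt-Co1 and mt-Cytb lost their calls with genes detected as a covariate, with Rplp0 at -1.35 and mt-Co1 at -1.07.

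Of 22 glycolysis and hypoxia genes, 13 fell and 1 rose (13 and 2 adjusted over the list alone; 9 and 5 under total-count scaling). The list median was -0.74, and -0.16 under total-count scaling (camera adjusted p = 1.2e-06, and adjusted p = 0.589 with an estimated correlation). The members that fell included the enzyme genes Pgam1 (2193 ± 399 to 594 ± 51.7 CPM, -1.89, SE 0.15, adjusted p = 3.8e-05), Pkm (-1.61), Aldoa (-1.38) and Gapdh (-2.03), whereas the hypoxia-responsive growth factor gene Vegfa rose by 1.79 (SE 0.34, adjusted p = 0.0030). Of 30 G1/S and replication genes, 16 fell and 0 rose (19 and 0 adjusted over the list alone; 2 and 1 under total-count scaling), with a median of -0.52 that became 0.09 under total-count scaling (camera adjusted p = 3.2e-07, and adjusted p = 0.589 with an estimated correlation). The replicative helicase genes Mcm6, Mcm7 and Mcm3 fell by 1.13, 1.10 and 0.85, and the calls of Mcm3 and of the clamp gene Pcna (-0.75) were lost under total-count scaling. Gapdh kept its call with genes detected as a covariate, and Pgam1 (-1.68), Pkm, Aldoa, Mcm6, Mcm7, Mcm3 and Pcna lost theirs. The 28 G2/M genes had 0 calls in edgeR by either adjustment, with 2 at an unadjusted p under 0.05, and 13 rose under total-count scaling (camera adjusted p = 0.529). The list passed as lower without KO replicate 3 (median -0.24, adjusted p = 0.022). Without KO replicates 2 and 3 its median was -0.45 (adjusted p = 4.3e-05) against 0.05 with all libraries, 0.63 under total-count scaling, and adjusted p from 4.3e-05 to 0.974 over its alternatives.

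Of 24 MYC and ribosome biogenesis genes, 14 fell and 1 rose (17 and 1 adjusted over the list alone; 2 and 3 under total-count scaling), with a median of -0.50 that became 0.08 under total-count scaling (camera adjusted p = 5.7e-05, and adjusted p = 0.617 with an estimated correlation). The nucleolar genes Npm1 and Nhp2 each fell by 1.10. Of 20 cholesterol synthesis genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.61, camera adjusted p = 1.4e-04, and adjusted p = 0.589 with an estimated correlation). Under total-count scaling 4 of these rose and 3 fell, with a median of -0.03. Sqle, which encodes squalene epoxidase, fell by 2.03 on the log2 scale (SE 0.27, adjusted p = 4.7e-04). Of 23 histone chaperone and heterochromatin genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone; 1 and 9 under total-count scaling), with a median of -0.31 that became 0.26 under total-count scaling (camera adjusted p = 0.041, and adjusted p = 0.622 with an estimated correlation). That list call was lost without KO replicate 4 (adjusted p = 0.080) and under the stricter count filter (adjusted p = 0.23), with a range of 3.1e-06 to 0.622 over its alternatives. H3f3a, a gene for histone H3.3, fell by 1.29 (SE 0.16, adjusted p = 2.7e-04) and the H3K9 methyltransferase gene Setdb1 rose by 0.58 (SE 0.12, adjusted p = 0.0041). Sqle kept its call with genes detected as a covariate, and Npm1, Nhp2, H3f3a (-1.15) and Setdb1 lost theirs. Ribosomal protein, Gapdh and H3.3 genes have many processed pseudogenes, so their counts depend on how shared reads were assigned.

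The type I interferon list rose, with 16 of 29 measured members higher and 0 lower (18 and 0 adjusted over the list alone, 28 and 0 under total-count scaling; median 1.24, and 1.86 without FL replicate 4; camera adjusted p = 8.9e-08, and adjusted p = 0.589 with an estimated correlation). Only KO mice carried Mx1-Cre, so the rise of this list cannot be told apart from an effect of that transgene, which was not tested. Ddx58, the RNA sensor RIG-I, rose from 2.48 ± 0.821 to 14.3 ± 1.01 CPM (2.53, SE 0.24, adjusted p = 8.6e-05). The antiviral genes Oas2, Rtp4 and Ifi44 rose by 4.10, 4.42 and 6.05 to 10.9 ± 2.43, 4.63 ± 1.23 and 3.33 ± 1.33 CPM. Oas2 was at 5.29 without FL replicate 4, and Ifi44 at 7.42 without FL replicate 1. With genes detected as a covariate Rtp4 and Ifi44 kept their calls, and Ddx58 (2.36) and Oas2 (4.01) lost theirs. The erythroid list also rose, with 5 of 9 measured members higher by either adjustment and 9 under total-count scaling (median 1.75, camera adjusted p = 0.032, and adjusted p = 0.589 with an estimated correlation). Its called members were low in KO, with Hbb-bs, an adult beta-globin gene, at 3.93 ± 4.59 CPM (4.51, SE 0.93, adjusted p = 0.0048), a call lost with limma-voom and with the covariate (2.25). Without KO replicate 3 it was at 3.30. The erythroid call was lost without KO replicate 3 (median 0.99, adjusted p = 0.081) and without KO replicates 2 and 3 (adjusted p = 0.059), with a range of 3.0e-04 to 0.589 over its alternatives. Its median ran from 0.99 without KO replicate 3 to 3.65 without KO replicate 1. It was also above 1.75 by over 1.5 times without FL replicate 1, 2, 3 or 4.

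**Figure D3:**
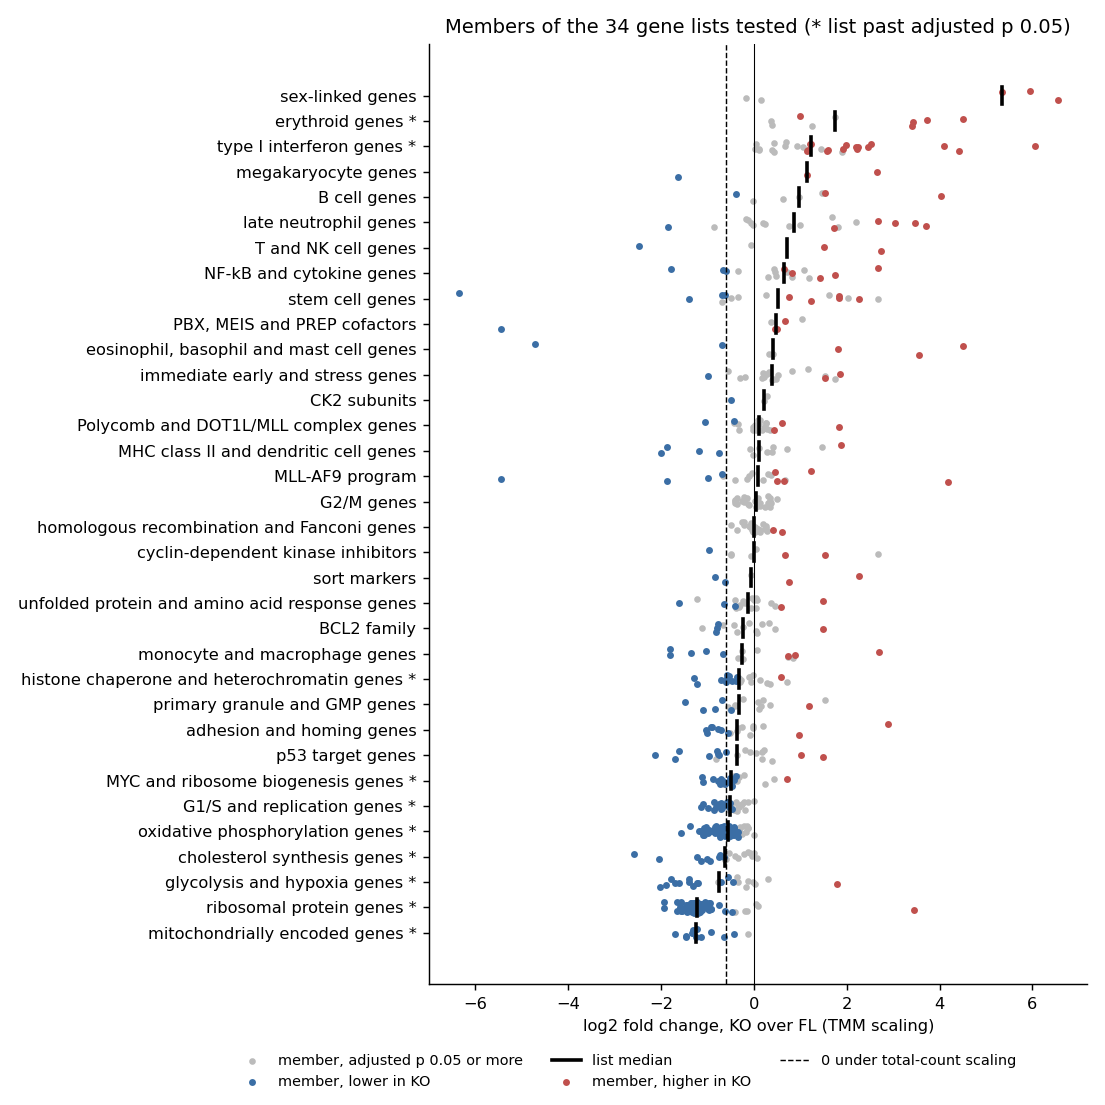
Log2 fold change of KO over FL under TMM scaling (horizontal axis) for each member of the 34 tested gene lists (vertical axis), with red and blue points for members past adjusted p 0.05, grey points for the others, black bars for list medians and an asterisk for lists past camera. Ribosomal protein and mitochondrially encoded genes lie furthest left; the dashed line marks 0 under total-count scaling, and every list whose median lies between that line and 0 has a positive median under that scaling.

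Markers of other blood cells moved in the same libraries. Of 7 measured eosinophil, basophil and mast cell genes, 3 rose and 2 fell by either adjustment (4 and 1 under total-count scaling). Prg2, the eosinophil major basic protein gene, went from 35.8 ± 26.6 to 421 ± 318 CPM (3.56, SE 0.70, adjusted p = 0.0038) and Epx, eosinophil peroxidase, from 5.05 ± 5.65 to 114 ± 88.8 CPM (SE 0.90, adjusted p = 0.0041). With genes detected as a covariate Prg2 had a log2 fold change of 0.013 and Epx 0.90, and neither passed. Epx stood at 41.2, 156, 219 and 39.4 CPM in KO replicates 1 to 4. Late neutrophil genes had 5 higher and 1 lower of 18 (6 and 1 adjusted over the list alone; 8 and 1 under total-count scaling) and passed camera as higher without KO replicate 1 (adjusted p = 0.026; 0.026 to 0.83 over its alternatives), with the neutrophil secretory genes Retnlg at 3.72 (SE 0.47, adjusted p = 3.4e-04), Lrg1 at 3.03 (SE 0.44, adjusted p = 6.6e-04) and Mmp8, a collagenase gene, at -1.84 (SE 0.35, adjusted p = 0.0033). Lrg1 was at 3.67 without FL replicate 1. Of 16 primary granule and GMP genes, 5 fell and 1 rose by either adjustment, against 2 and 7 under total-count scaling. Srgn, a granule proteoglycan gene, fell by 1.10 (SE 0.17, adjusted p = 0.0012), Ctsg (cathepsin G) by 0.83, a call lost under total-count scaling and without KO replicates 2 and 3. Csf3r, the G-CSF receptor gene, rose from 70.1 ± 13.4 to 161 ± 17.8 CPM (SE of the log2 fold change 0.15, adjusted p = 3.4e-04). Of 14 monocyte and macrophage genes, 5 fell and 3 rose (5 and 5 adjusted over the list alone; 3 and 5 under total-count scaling), including Ly6c2 (-1.35, SE 0.23, adjusted p = 0.0018) and Csf1r (0.73, SE 0.17, adjusted p = 0.0083). Of 13 MHC class II and dendritic cell genes, 4 fell and 1 rose by either adjustment (3 and 5 under total-count scaling), with H2-DMa at -1.19 (SE 0.17, adjusted p = 5.6e-04). With the covariate the calls of Retnlg (3.47), Lrg1 (2.92), Mmp8 (-1.62), Srgn (-1.25), Ctsg (-0.73), Csf3r (1.4), Ly6c2 (-1.37), Csf1r (1.32) and H2-DMa (-0.91) were also lost.

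The B cell list had 2 higher and 1 lower of 7 (4 and 1 adjusted over the list alone; 5 and 0 under total-count scaling), with the light chain gene Igkc at 1.02 ± 0.590 CPM in KO. The list did not pass camera in the main fit (adjusted p = 0.112). It passed as higher without FL replicate 1, 2, 3 or 4 or KO replicate 1 (camera adjusted p 0.0030 to 0.033). It also passed as higher without a count filter (0.0049, with a range of 0.0030 to 0.589 over its alternatives). The T and NK cell list had 2 higher and 1 lower of 4, and the megakaryocyte list 2 higher and 1 lower of 3, each by either adjustment and under total-count scaling. The stromal and endothelial list had too few measured members to test. Of 5 sex-linked genes, 3 rose by either adjustment, all Y-linked, and 4 under total-count scaling. Ddx3y, Eif2s3y and Uty together had 2, 4, 6 and 6 reads in FL replicates 1 to 4 and 100, 319, 611 and 149 reads in KO replicates 1 to 4. Igkc, Ddx3y and Eif2s3y did not pass with genes detected as a covariate.

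The libraries differed in breadth as well. Thinned to an equal total, KO libraries held reads for 33776 ± 4118 genes and FL libraries for 24083 ± 981 genes (SD, n = 4 each). Olfactory and vomeronasal receptor genes are not known to be used by blood cells. Without TMM scaling they summed to 164, 402, 468 and 170 CPM in KO replicates 1 to 4 and to 64.7 to 110 CPM in FL. KO replicates 2 and 3 were highest in this sum, in genes detected, in Y-linked reads and in Epx and Prg2. Whether these share a source was not tested. Mitochondrial mRNA made up 1.25 ± 0.0568% of counts in KO and 1.96 ± 0.149% in FL. The share of higher genes among those called ran from 91.9% in the lowest of the 10 abundance bins to 3.12% in the highest. Without KO replicates 2 and 3 the counts of members that rose and fell were 0 and 64 for ribosomal proteins, 0 and 32 for oxidative phosphorylation, 0 and 10 for mitochondrially encoded genes, 1 and 10 for glycolysis, 0 and 15 for G1/S, 0 and 4 for MYC, 0 and 8 for cholesterol synthesis, 1 and 3 for histone chaperones, 12 and 0 for interferon and 1 and 0 for erythroid genes. In that order the list medians were -1.11, -0.62, -1.13, -0.56, -0.69, -0.47, -0.73, -0.36, 1.39 and 1.21.

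**Figure D4:**
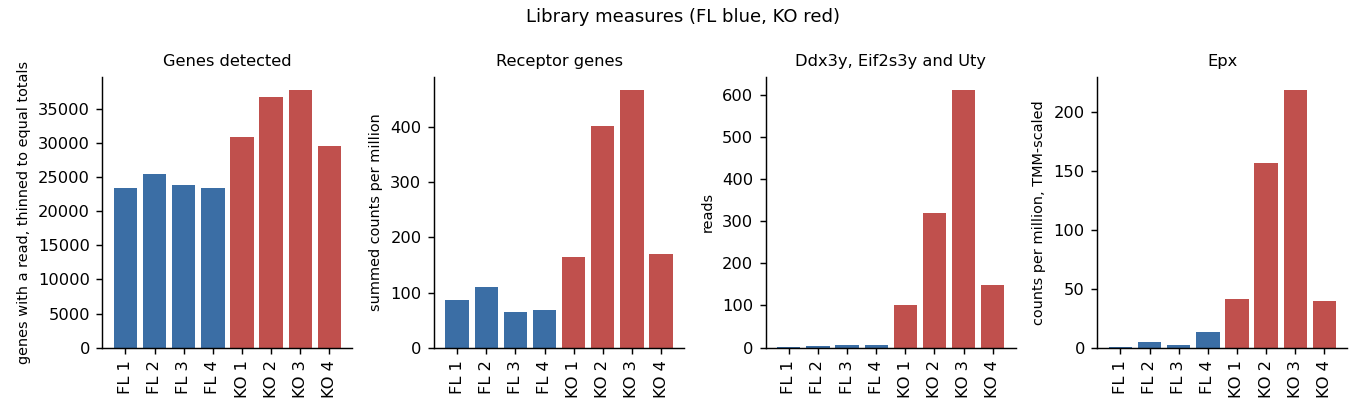
Bars for each of the 4 FL (blue) and 4 KO (red) libraries show genes with a read after thinning to equal totals, summed CPM of receptor genes without TMM scaling, reads of Ddx3y, Eif2s3y and Uty, and Epx in TMM-scaled CPM. All 4 measures are higher in each KO library than in each FL library, with the highest values in KO replicate 3 (37801 genes, 468 CPM, 611 reads and 219 CPM).

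The lists of this paragraph did not pass camera in the main fit. Without a count filter camera called the adhesion (adjusted p = 5.4e-05), p53 (3.0e-04) and unfolded protein (0.0031) lists lower. It also called the BCL2 (0.0067) and homologous recombination (0.038) lists lower there. Camera compares a list with the other genes. The median log2 fold change of all tested genes was 0.90 without the filter, against 0.05 in the main fit. These calls therefore mean lower than that level, and they do not show a fall of the lists themselves. With the replicate block NF-kB genes passed camera as higher (adjusted p = 0.049). Of 19 p53 target genes, 8 fell and 2 rose, against 2 and 6 under total-count scaling, and the list passed as lower without FL replicate 4 (adjusted p = 0.023; 3.0e-04 to 0.589 over its alternatives). Its called members included the exonuclease gene Aen (-1.60, SE 0.18, adjusted p = 1.7e-04) and Plk2, a kinase gene that rose from 1.98 to 5.58 CPM (SE of the log2 fold change 0.26, adjusted p = 0.0021). Of 17 adhesion and homing genes, 7 fell and 2 rose (9 and 2 adjusted over the list alone), against 1 and 6 under total-count scaling. The list passed camera as lower without FL replicate 2, 3 or 4 or KO replicate 4 (adjusted p 0.024 to 0.041; 5.4e-05 to 0.589 over its alternatives). Selplg, the P-selectin ligand gene, fell by 1.02 (SE 0.11, adjusted p = 1.6e-04), and Cd96, a surface marker of leukaemia stem cells, rose by 2.89 (SE 0.53, adjusted p = 0.0026). Among 8 cyclin-dependent kinase inhibitors, 2 rose and 1 fell (3 and 1 adjusted over the list alone; 5 and 0 under total-count scaling): Cdkn2c rose by 1.52 (SE 0.30, adjusted p = 0.0037), Cdkn1b by 0.66, and Cdkn1a fell by 0.96 (SE 0.23, adjusted p = 0.010). The Cdkn1a call was lost under total-count scaling (-0.40). Without KO replicates 2 and 3 the calls of Cdkn1a (-1.03) and Cdkn1b (0.65) were lost, at log2 fold changes close to the main ones. The BCL2 family had 1 higher and 3 lower of 15 (5 and 0 under total-count scaling), with the death agonist gene Bid at -0.82 (SE 0.12, adjusted p = 6.1e-04), a call lost under total-count scaling. NF-kB and cytokine genes had 5 higher and 3 lower of 17 (6 and 3 adjusted over the list alone; 12 and 1 under total-count scaling), with the smallest p at Ptgs2, cyclooxygenase 2 (2.68, SE 0.37, adjusted p = 5.1e-04). The unfolded protein and amino acid response list had 2 higher and 3 lower of 20 (9 and 1 under total-count scaling), with the serine synthesis gene Psat1 at -1.61 (SE 0.20, adjusted p = 3.5e-04). Immediate early and stress genes had 2 higher and 1 lower of 19 (11 and 0 under total-count scaling), and 0 and 0 adjusted over the list alone by edgeR, with 6 at an unadjusted p under 0.05. The list passed camera as higher without KO replicate 4 (adjusted p = 0.022; 0.022 to 0.988 over its alternatives). Of 26 homologous recombination and Fanconi genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone; 17 and 0 under total-count scaling). Without a count filter that list passed camera as lower than other genes (adjusted p = 0.038, and 0.038 to 0.998 over its alternatives). Its median there was -0.041. Polycomb and DOT1L/MLL complex genes had 3 higher and 2 lower of 23 (18 and 0 under total-count scaling). Of the 3 subunits of CK2, the kinase named in the series title, Csnk2b fell by 0.49 (SE 0.12, adjusted p = 0.0099), which turned to 0.11 under total-count scaling and did not pass without KO replicates 2 and 3. The other two did not pass. Under total-count scaling 2 subunits rose and 0 fell, and under the stricter filter 1 rose and 1 fell. With genes detected as a covariate Cd96 and Psat1 kept their calls. Lost calls and their log2 fold changes there were Aen (-1.78), Plk2 (1.96), Selplg (-0.98), Cdkn2c (1.62), Cdkn1b (0.56), Cdkn1a (-1.38), Bid (-0.61), Ptgs2 (3.10) and Csnk2b (-0.57). Counts adjusted over the list alone equalled those over all genes where only 1 pair is given. Across the 24 lists that did not pass, camera's adjusted p ran from 0.075 for adhesion genes to 0.981 for homologous recombination genes. Median, mean and camera differed in sign for the MLL-AF9 program (camera up), for the cofactors (0.48, -0.40, up), the sort markers (-0.06, 0.30, down), MHC class II genes (0.11, -0.05, down), G2/M genes (0.05, 0.01, down) and kinase inhibitors (-0.0046, 0.36, up).

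Total-count scaling moved the median log2 fold change of all genes from 0.05 to 0.64, a shift of 0.59, and called 9012 genes higher and 886 lower in place of 2256 and 2597. With the number of genes detected as a covariate, 205 genes passed, 107 higher and 98 lower, Dek, Pbx3, Gdf3, Atp9a and Prdm16 among them. Without KO replicates 2 and 3, 2342 genes passed, 1000 higher and 1342 lower.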

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

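Tests of deeper sequencing, of X-linked partner reads and of male genomic DNA were chosen after the result they bear on was seen.

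Single libraries far from the other 3 of their group were found in 21 of 268 groups of values, where chance gives about 13.4; 8 were in FL replicate 4, 4 each in FL replicate 3 and KO replicate 3, and 3 in FL replicate 2. FL replicate 4 stood high for Myb (881 CPM), Ear6 (6.60 CPM), Ear2 (5.77 CPM), Oas2 (1.73 CPM), Cd96 (2.23 CPM), Ly6a (0.700 CPM) and mitochondrial rRNA (3.76% of counts) and low for Aspa (24.4 CPM). FL replicate 3 stood high for Lipo3 (0.099 CPM), H2-Ab1 (18.5 CPM), Nhp2 (293 CPM) and Bax (96.9 CPM), and FL replicate 2 for Zfp182 (0.423 CPM), Nutm1 (2.17 CPM) and Lpl (128 CPM). KO replicate 3 stood low for Cd34 (374 CPM), Kit (107 CPM) and Csf3r (134 CPM) and high for Car2 (4.98 CPM). Tlr13 was high in KO replicate 4 (4.83 CPM), and mitochondrial mRNA was low in KO replicate 2 (1.17% of counts). Olfactory and vomeronasal receptor genes, which are in none of the fixed gene lists, summed to a mean of 300.9 CPM in KO and 82.2 CPM in FL, without TMM scaling.

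By edgeR, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many as 4853 called genes. The highest other split gave 0 calls, or 1613 genes at an unadjusted p under 0.05 against 6891. Every other split mixes KO and FL libraries, so the group difference widens its spread and few calls could arise. The splits show that the calls follow the labels, and they cannot exclude a chance difference between leukaemias. No other tool was run on the splits. The largest distance of an autosome's median log2 fold change from that of all genes was 0.108, which argues against a whole-chromosome copy number difference of 0.3 or more.

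KO libraries detected more genes than FL libraries. Deeper sequencing is argued against, because the difference was 40.25% of the FL mean after thinning to equal totals; reads were matched and not distinct molecules, since the amplified libraries carry no identifiers. Genomic DNA or unspliced RNA may contribute. Receptor gene CPM per total counts was 3.66 times as high in KO, and every KO library exceeded every FL library. TMM factors were higher in KO, so that scaling would lower the ratio. The preset limit for this test was not checked under TMM scaling, so whether the ratio would still pass it there is unresolved. The receptor ratio is per total counts, while the lineage medians below were read first under TMM scaling. The receptor and lineage tests are therefore not on the same scale, and neither explanation is preferred. Cells of other blood lineages cannot be told apart from genomic or unspliced reads. Under TMM scaling the lowest of the 4 lineage lists' medians was 0.721, for T and NK cells. This is under the 1 expected of all 4 lists if such cells were the cause, and above the 0 that would argue against them. Under total-count scaling the medians were 1.31 to 2.37, all above 1, so the reading depends on the scaling. The 0.721 rests on 4 of 14 T and NK members. The sort removes lineage-positive cells. An effect of Dek loss stays open and untested, because these measures follow the groups.

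Ribosomal protein, oxidative phosphorylation and glycolysis genes were lower in KO. A bias of transcript length and GC content is argued against as the whole cause: after its trend was removed the medians were -1.21, -0.53 and -0.70, the closest to 0 being -0.53. A loss of range, in which abundant genes fall as a class, could account for much of the pattern. After the abundance trend was removed the medians were -0.41 (95% bootstrap interval -0.46 to -0.36), -0.306 (-0.36 to -0.27) and -0.35 (-0.63 to -0.19). The upper limit lay below the preset -0.3 for ribosomal protein genes and not for the other lists. These intervals resample the genes of a list as if independent, and not the libraries. The estimated correlations were 0.73 for ribosomal protein, 0.54 for oxidative phosphorylation and 0.10 for glycolysis genes, so the intervals are too narrow. Loss of range cannot be told apart from a change in these genes, ribosomal protein genes included. The scaling matters too, since oxidative phosphorylation genes had a median of 0.03 under total-count scaling. Dek loss stays open and untested.

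Y-linked transcripts appeared in the KO libraries. Reads from X-linked partner genes are argued against, because the ratio of Y to partner reads was 80.85 times as high in KO as in FL. Male genomic DNA alone is argued against, because Y gene CPM per kb was at least 4.26 times that of the silent receptor genes in each KO library. The Y reads were 0.548, 2.36, 4.62 and 0.787% of the partner reads in KO replicates 1 to 4. RNA from a minority of male cells may be present, a hypothesis that was not tested further, and the sex of the mice is not in the labels used here.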

How the results depend on the processing

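Total-count scaling, leaving out KO replicates 2 and 3 together, and the test against a log2 fold change of 1 were tests chosen after the data were seen.

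Main counts were 4853 genes, 2256 higher and 2597 lower. DESeq2 called 5660 genes and limma-voom 5671, sharing 4847 and 4656 with the main test; RLE factors gave 4851 and upper-quartile factors 4863. Without a count filter 3647 genes were higher, and the stricter filter, which tests fewer genes, left 3140 genes with 1368 higher. With genes detected as a covariate 205 genes passed (107 higher, 98 lower), 193 shared with the main test; the covariate follows the groups closely, and the cause was not tested. Under total-count scaling 9898 genes passed (9012 higher, 886 lower), which follows from its shift of all log2 fold changes by 0.59. Without KO replicates 2 and 3, with fewer libraries, 2342 passed (1000 higher, 1342 lower), 2199 of them shared. The test against a log2 fold change of 1 gave 712 (390 higher, 322 lower), and 2562 called genes had a change of at least 1. Leaving out each library in turn gave 3397 to 5033 genes, 1459 to 2443 higher and 1938 to 2590 lower; the lowest came without KO replicate 2.

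Replicate numbers gave no clear sign of pairing. Same-numbered deviations from the group means correlated across genes at 0.047, 0.019, 0.029 and 0.024, and other pairs at -0.157 to 0.072. These values cannot exclude a shared day or batch. The replicate block gave 4339 genes, 4123 of them shared.

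Of 123 genes, 123 kept direction and side of the threshold with DESeq2 and with upper-quartile factors, 97 under total-count scaling, 94 without KO replicates 2 and 3, and 28 with the covariate. Under total-count scaling 7 turned, from the shift: Myb to 0.27, Top2a to 0.35, Bub3 to 0.23, Anp32e to 0.023, H3f3b to 0.022, Csnk2b to 0.11 and Wdr5 to 0.17. Myb was 0.28 with the covariate and -0.58 to 0.16 with each library left out, positive without FL replicate 4. Without a count filter edgeR called it lower (-0.44, adjusted p = 0.032).

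The number of lists past camera was 10. It was 0 with an estimated correlation, with 1 at an unadjusted p under 0.05, and 20 without a count filter. Without that filter the median log2 fold change of all tested genes was 0.90, against 0.05 in the main fit. Camera compares a list with the other genes, so its directions there are relative to that level. For lists that did not pass, the direction of the test turned in some settings, and the values here are list medians. Without a count filter this held for the MLL-AF9 program (0.21), stem cell genes (0.95), cyclin-dependent kinase inhibitors (-0.32), homologous recombination genes (-0.041, which passed as lower, adjusted p = 0.038; range 0.038 to 0.998), CK2 subunits (0.17), Polycomb genes (0.076) and immediate early genes (0.35). It held under the stricter filter for stem cell genes (-0.42). Without KO replicates 2 and 3 it held for stem cell genes (0.26), sort markers (0.061), kinase inhibitors (-0.30) and homologous recombination genes (-0.25), and with the replicate block for homologous recombination genes (-0.011) and CK2 subunits (0.21). With each library left out, medians ran from 0.025 to 0.34 for the MLL-AF9 program, 0.22 to 1.07 for stem cell genes, -0.20 to -0.014 for sort markers, 0.036 to 0.36 for MHC class II genes, 0.42 to 1.72 for T and NK cell genes, -0.24 to 0.26 for G2/M genes, -0.19 to 0.024 for kinase inhibitors, -0.10 to 0.10 for homologous recombination genes and 0.15 to 0.23 for CK2 subunits. Lists that passed only in some settings were, without a count filter, the homologous recombination list and 9 others; with each library left out, 13 cases, among B cell, adhesion, p53, late neutrophil, G2/M and immediate early genes; with the replicate block, NF-kB genes (0.60, adjusted p = 0.049; range 0.049 to 0.711); and without KO replicates 2 and 3, G2/M (-0.45) and sex-linked genes (3.50). The cause of these changes was not tested.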

Other observations

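The limits and genes in this part were chosen after their values were seen. With a group mean under 0.5 CPM in 1 group and of 5 CPM or more in the other, 21 called genes were high in KO and 7 in FL. Besides Psma8, Gdf3 and Bcl11a, the first set held Sdc2, a heparan sulfate proteoglycan (log2 fold change 8.77, SE 0.61, adjusted p = 1.7e-05 by edgeR), the small GTPase Rab38 (6.85, SE 0.49, adjusted p = 1.9e-05), the signalling adaptor Grb14 (4.69, SE 0.32) and Eps8, an actin regulator (4.14, SE 0.27). The second set held Prdm16, Rap1gap, a GTPase activator of RAP1 (-5.34, SE 0.36, adjusted p = 1.6e-05), the peptide transporter Slc15a2 (-5.08, SE 0.38, adjusted p = 2.7e-05) and the serine protease gene Hpn (-4.50, SE 0.52, adjusted p = 2.1e-04). Among abundant genes, Slpi, a secreted inhibitor of neutrophil proteases, fell from 4878 ± 643 to 544 ± 143 CPM (SD, n = 4 each; log2 fold change -3.16, SE 0.21, adjusted p = 1.3e-05).

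Genes of the mitochondrial chromosome had a median log2 fold change of -1.23 over 19 genes, while the autosomes' medians lay between -0.06 (chromosome 15) and 0.12 (chromosome 1). Actb took 0.746 ± 0.0924% of counts in KO and 1.52 ± 0.332% in FL. Sense intronic transcripts summed to 343 ± 14.0 CPM in KO and 184 ± 43.2 CPM in FL, without TMM scaling. Xist had a log2 fold change of -0.16 under TMM scaling (SE 0.13, adjusted p = 0.39 by edgeR), and without that scaling it stood at 366 to 495 CPM in FL and 489 to 643 CPM in KO. Epx had 2221, 7168, 9019 and 2431 reads in KO replicates 1 to 4 and 20, 190, 78 and 524 reads in FL replicates 1 to 4.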
